A study of Homo sapiens with 18 samples.

How the data were processed

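RNA was measured by sequencing in JJN3, a human multiple myeloma cell line, after DMSO or the KDM6 histone demethylase inhibitor GSK-J4. The 18 libraries fell into 6 groups of 3 by treatment and by time, at 3, 6 and 24 h. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit. The authors deposited raw read counts per Ensembl gene, as whole numbers with no normalization. HISAT2 version 2.1.0 and the build hg19 are named in the submitters' processing notes. The counting tool, its annotation and its use of strand are not given in the sources used here. How reads shared by near-identical genes, such as metallothionein or heat shock paralogs, or by antisense or overlapping genes, were counted is therefore not known. The values of such genes are uncertain. The table held 2 further columns that matched no sample's labels, and these were not used.

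Libraries held 5.43 to 19.84 M counts (median 17.96 M). DMSO at 6 h, replicate 2, had 5.43 M and the next lowest had 13.04 M. The labels give a number 1 to 3 to each library of a group. Nothing states that these came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group agreed within sampling noise, since the lowest chi-square per degree of freedom was 1.69, so all were kept as separate replicates. Symbols were taken from a table of current names, which gave one to 39538 of the 57773 identifiers. Of the 16389 genes tested, 1674 had no symbol and are named by identifier where they appear. No coordinates are given, because the reference at hand was of another build.

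Counts were filtered with filterByExpr over the 6 groups, scaled by TMM, and fitted with edgeR 4.0.16 in R 4.3.3 in one quasi-likelihood model of all 18 libraries with 12 residual degrees of freedom. Each GSK-J4 group was compared with DMSO of the same time by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the 16389 genes and a threshold of 0.05. The differences between those effects, and between DMSO groups, were contrasts of the same fit. Standard errors (SE) were the log2 fold change divided by the square root of F. Levels are TMM-scaled counts per M (CPM), as mean ± SD with n = 3. Against vehicle groups with no counts, a fold was computed from a floor of 3 counts over the group and is a lower bound for counting error only.

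Before the data were examined, 39 gene lists were fixed, of which 38 had 3 or more measured members. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 38 lists. An estimated correlation and fry were alternatives. The genes named were also set by a rule fixed then. It took KDM6A, KDM6B and 10 stress and myeloma genes at every time, the 10 largest rises and falls with a mean of at least 5 CPM and no overlap between treated and vehicle libraries, up to 4 members per list, and the 5 most positive and negative differences between times. Immunoglobulin genes were left out, and some genes that the rule took are not reported here. Another 6 lists, of AHR targets, notochord and chordoma markers, amino acid transporters, haem synthesis, BMP and ID targets and fatty acid synthesis, were added once the values had been seen.

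The alternatives planned were DESeq2 size factors, upper quartile or library size scaling, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, a fit of only the groups compared, the label number as a block, each library left out in turn, a 2-fold minimum and an adjusted p under 0.01. A correction of each library's trend with GC content, which 97.3% of tested genes had a value for, and the removal of DMSO 6 h replicate 2 from the fits of comparisons that do not hold it were chosen after seeing the data. The model was tested on simulated counts for the same 16389 genes. These were drawn independently for each gene, with no GC trend and no library set apart from its group. The false calls below therefore do not cover such features of the real libraries. At 24 h it recovered 31.3% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 84.8% of those changed 4-fold, with 5 false calls among 129. False calls were 3 among 121 at 3 h and 5 among 128 at 6 h. For the differences between times they were 12 among 183 for 3 and 6 h and 16 among 187 for 6 and 24 h, both above the 5% that the threshold aims at, and 4 among 167 for 3 and 24 h. Figures were drawn with matplotlib 3.10.9.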

Results

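The transcriptome of JJN3 myeloma cells was measured after 3, 6 or 24 h with GSK-J4 or with DMSO as vehicle, in 3 libraries per group of 5.43 to 19.84 M counts each. The comparisons bear on metal and stress responses to the inhibitor, the subject of the series. GSK-J4 libraries lay close together, with an SD of log2 CPM from the rest of their group of 0.104 to 0.181. DMSO libraries lay further apart, at 0.159 to 0.287 at 3 h, 0.165 to 0.284 at 24 h and 0.39 to 0.891 at 6 h. DMSO 6 h replicate 2 had the highest distance. Those of DMSO 6 h replicates 1 and 3, 0.39 and 0.578, were taken from means that hold replicate 2. These replicates 1 and 3 differed by a chi-square per degree of freedom of 21.5, near the 21.2 between DMSO 3 h replicates 1 and 2. Against DMSO 6 h replicate 2 they had 68.4 and 93.1. Across genes, the deviation of DMSO 6 h replicate 2 from the mean of all 18 libraries correlated with GC content at 0.635. Correlations with GC content below are all taken from that mean, so they can also hold effects of treatment and time. The mitochondrial share of DMSO 6 h replicate 2 was 0.46% against 1.01% to 3.86% in the other 17 libraries.

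**Figure D1:**
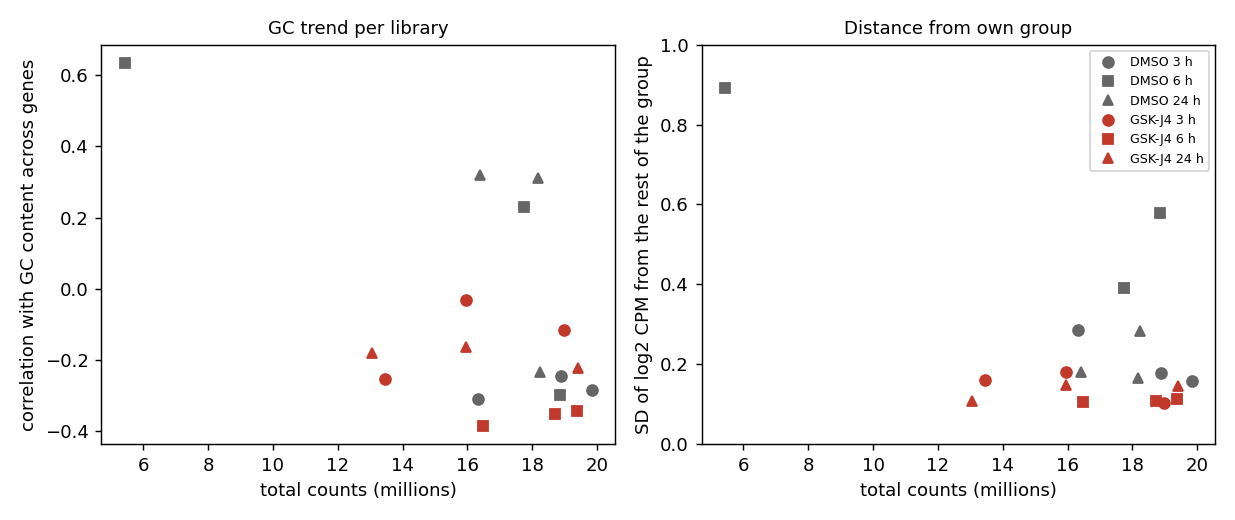
Each point is 1 library. The left panel plots the correlation of its deviation from the mean of all 18 libraries with GC content across genes. The right panel plots its SD of log2 CPM from the rest of its group. Both are set against total counts (M). DMSO 6 h replicate 2 sits apart at 5.43 M counts, 0.635 and 0.891.

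After 3 h, metallothioneins, small cysteine-rich proteins that bind zinc and copper, rose together with the zinc exporter SLC30A1. All 7 measured metallothioneins rose. MT2A went from 1.04 ± 0.277 to 85.3 ± 1.84 CPM (SD, n = 3), a log2 fold change of 6.38 (SE 0.207, adjusted p = 9.13e-12). MT1G rose by 5.77 and MT1X by 4.18 on the log2 scale. MT1M had no counts in the vehicle and was at least 17.7-fold higher. SLC30A1 rose from 56.9 ± 3.00 to 240.4 ± 17.3 CPM (SD, n = 3), a log2 fold change of 2.08. It was the 1 member of 27 zinc and copper transport genes that passed.

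Targets of ATF4, the transcription factor of the integrated stress response, also rose at 3 h. Of 31 measured, 10 rose, 0 fell and 21 did not pass, and 16 rose when adjusted over the list alone. CHAC1, a glutathione-degrading enzyme, rose by 2.28, INHBE by 1.76, DDIT4 by 1.74 and SESN2 by 1.30 on the log2 scale. DDIT3, which encodes CHOP, rose from 3.54 ± 0.299 to 7.40 ± 0.884 CPM (SD, n = 3, adjusted p = 0.00234). ATF4 itself had a log2 fold change of 0.21 and did not pass. In the other direction, 3 of 23 heat shock genes fell, and 8 when adjusted over the list alone, with HSPA8 at a log2 fold change of -0.81, DNAJB1 of -0.77 and BAG3 of -0.61. In the same comparison correlations with GC content were -0.310 to -0.245 with DMSO and -0.254 to -0.033 with GSK-J4, and DMSO 3 h replicate 2 differed from replicates 1 and 3 by a chi-square per degree of freedom of 21.2 and 19.0, against 1.88 between those. CYP1A1 and CYP1B1, oxidases that the aryl hydrocarbon receptor (AHR) induces, had log2 fold changes of -2.41 and -1.79.

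In all, 44 genes changed at 3 h, 31 higher and 13 lower. Camera called 9 lists. Metallothioneins, ATF4 targets, heat shock (adjusted p = 0.00914 with an estimated correlation) and hypoxia (0.00642) held with an estimated correlation. Of 24 hypoxia genes 3 rose and 0 fell, and 6 rose when adjusted over the list alone. They were VEGFA, an angiogenic growth factor, by 0.56, and DDIT4 and STC2, which were also on the list of ATF4 targets. Whether these rises were apart from the ATF4 response was not tested. The other 5 were lost, with an adjusted p of 0.584 for ribosomal proteins, 0.424 for mitosis, 0.488 for proteasome, and 0.539 for both oxidative phosphorylation and JmjC demethylases, and none of these had a member that passed. Without DMSO 6 h replicate 2, which widens the shared spread, 114 genes changed at 3 h. The count was 27 without DMSO 3 h replicate 2 or GSK-J4 replicate 1 and 28 without GSK-J4 replicate 2 or 3. The list ribosomal proteins at 3 h turned to the other direction, not called, without DMSO 3 h replicate 2 (adjusted p = 0.765, and 8.98e-07 to 0.765 with a library left out).

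After 6 h all 7 metallothioneins were above vehicle. MT2A was at 202 ± 15.4 CPM against 1.49 ± 0.755 (SD, n = 3), a log2 fold change of 7.32 (SE 0.216, adjusted p = 1.7e-12), and MT1G had a log2 fold change of 7.46. Against 3 h the fold was larger for MT1G and MT1H, by 1.69 and 1.95 (adjusted p = 0.0426 and 0.0456), while the difference for MT2A, 0.94, did not pass (adjusted p = 0.472). Neither passed with only the groups compared in the fit. With a library of the comparison left out, MT1G passed without DMSO 6 h replicate 2 or 3 and MT1H without DMSO 3 h replicate 3 or DMSO 6 h replicate 2, and neither did otherwise. SLC30A1 remained up by 1.94. Of the 31 ATF4 targets, 23 rose, 0 fell and 8 did not pass, and over the list alone 26 rose and 1 fell. INHBE rose by 3.51, SLC7A11, the cystine transporter, by 2.49, and ASNS, asparagine synthetase, by 1.43. Of 17 one-carbon metabolism genes 4 rose and 0 fell (adjusted p = 0.164 with an estimated correlation), the serine synthesis enzymes PSAT1 by 1.54 and PSPH by 1.13, while PHGDH had a log2 fold change of 0.26 and did not pass. The unfolded protein response genes HERPUD1 and ERN1 rose by 1.24 and 0.92, though that list went both ways, with 3 higher and 3 lower. Of 23 heat shock genes, 10 fell, and 15 adjusted over the list alone (adjusted p = 0.0747 by camera with an estimated correlation), BAG3 having a log2 fold change of -0.97. In the same comparison DMSO 6 h replicates 1, 2 and 3 had correlations with GC content of 0.231, 0.635 and -0.298 and mitochondrial shares of 1.99%, 0.46% and 3.46%, against -0.386 to -0.343 and 2.95% to 3.47% with GSK-J4. CYP1A1 stayed low at -2.64.

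Counts at 6 h moved with single libraries of both groups. With all 18 libraries, 597 genes changed, 292 higher and 305 lower. With only the 6 libraries of the comparison in the fit, 26 changed, 24 higher and 2 lower, and DESeq2 called 2381, 801 higher and 1580 lower. Leaving out DMSO replicate 1 gave 2521, 855 higher and 1666 lower, and DMSO replicate 3 gave 4637, while leaving out GSK-J4 replicate 1, 2 or 3 gave 164, 187 or 167. Scaling by library size alone gave 329 higher and 183 lower genes. Without DMSO replicate 2 the count was 721. Of the 53 genes that fell 2-fold or more, 11 did so without that library. NKX2-5 at 6 h had a log2 fold change of -4.11 with it and -1.39 without it (adjusted p = 0.137, and 4.04e-66 to 0.503 over all alternatives), and RPL23AP74 at 6 h had -2.83 and -1.06 (adjusted p = 0.203, and 2.2e-38 to 0.503 over all alternatives). ATF4 at 6 h had 928 CPM in that library against 360 and 364 in the other vehicle libraries. Its log2 fold change was -0.04 with the library and 0.56 without it (adjusted p = 0.00109, and 0.000196 to 0.995 over all alternatives). Camera called 10 lists, of which ATF4 targets and metallothioneins held with an estimated correlation. Heat shock and cholesterol synthesis then had an adjusted p of 0.0747, one-carbon metabolism 0.164, MYC targets 0.272, and tRNA synthetases, DNA replication and glycolysis 0.485, with 0.635 for oxidative phosphorylation.

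**Figure D2:**
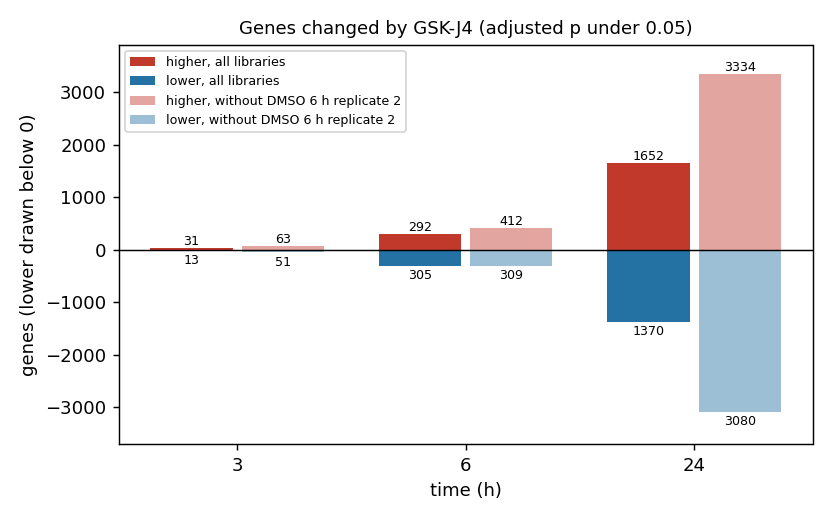
Bars give genes changed by GSK-J4 at each time, higher above 0 and lower below it, with all libraries (dark) and without DMSO 6 h replicate 2 (light). At 24 h they are 1652 and 1370 genes against 3334 and 3080.

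After 24 h, metallothioneins were still high, SLC30A1 was up by less than at 3 h, and the median fold of ATF4 targets was the highest of the 3 times. MT2A stood at 44.5 ± 6.04 against 0.991 ± 0.184 CPM (SD, n = 3), a log2 fold change of 5.48 (SE 0.205). SLC30A1 was up by 0.58. Of 31 ATF4 targets, 28 rose, 0 fell and 3 did not pass, and 29 rose over the list alone. DDIT3 rose by 3.10 (SE 0.157, adjusted p = 1.11e-09), INHBE by 4.39, CHAC1 by 3.44 and ASNS by 1.96, and ATF4 itself by 0.95. FGF21 had no counts in the vehicle and was at least 23.4-fold higher. ASS1, argininosuccinate synthase, rose from 24.1 ± 2.07 to 361 ± 16.3 CPM (SD, n = 3), a log2 fold change of 3.91.

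Other lists that rose at 24 h and held with an estimated correlation were one-carbon metabolism, the unfolded protein response and p53 targets, in the same comparison of vehicle libraries with GC correlations of 0.321, 0.31 and -0.233 and treated ones of -0.223 to -0.164. One-carbon metabolism had 8 of 17 members higher and 2 lower, with PSAT1 up by 2.18 and PHGDH, the first enzyme of serine synthesis, by 1.43. The unfolded protein response had 10 of 34 higher and 0 lower, with ERN1, the sensor IRE1, up by 1.98. Among p53 targets 7 of 22 rose and 1 fell. SESN2 rose by 2.56 and was also on the list of ATF4 targets, and BBC3, which encodes the death-promoting protein PUMA, rose by 1.26. Whether the rises of p53 targets were apart from the ATF4 response was not tested. Of 23 interferon-stimulated genes 10 rose, XAF1 by 2.22, and this call was lost with an adjusted p of 0.0548 with an estimated correlation. Of 20 tRNA synthetases 11 rose and 3 fell, WARS1 rising by 1.54, with an adjusted p of 0.142 with an estimated correlation.

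Heat shock, glycolysis, cholesterol synthesis, MYC target and histone genes fell at 24 h, and these calls held with an estimated correlation. Measures that can mark library quality differed between the same groups, though those of treated libraries can also hold effects of GSK-J4. DMSO 24 h replicates 2 and 3 had correlations with GC content of 0.321 and 0.31 and mitochondrial shares of 1.01% and 1.27%, against -0.223 to -0.164 and 2.12% to 2.26% with GSK-J4. DMSO 24 h replicate 1 had -0.233 and 3.58%, and differed from replicates 2 and 3 by a chi-square per degree of freedom of 31.1 and 28.2, against 2.31 between those. The lists were not run with the GC trend removed. Heat shock genes fell in 16 of 23 and, adjusted over the list alone, in 18, HSPA8 from 2801 to 1266 CPM with a log2 fold change of -1.15 and HSPH1 of -1.12. Of 20 glycolysis genes 17 fell, ALDOC with a log2 fold change of -1.15 and LDHA of -1.09. Of 25 cholesterol genes 15 fell, INSIG1, which holds the SREBP complex in the endoplasmic reticulum, with -1.08. Of 29 MYC targets 18 fell, FBL with -0.73, while MYC itself was at 896 ± 59.4 against 860 ± 26.0 CPM (SD, n = 3) and did not pass. Of 17 histone genes 7 fell, H1-3 with -2.25. Mitosis genes fell in 8 of 32, PLK1 with -1.14, a call lost with an adjusted p of 0.142 with an estimated correlation. Housekeeping controls were not steady, since 8 of 26 fell and 1 rose, ACTB with -0.80 and between -0.81 and -0.74 under the other scalings, with an adjusted p of 0.142 with an estimated correlation. The remaining calls lost had an adjusted p of 0.142 for hypoxia, where 10 of 24 fell and 4 rose, 0.234 for DNA replication and for proteasome, and 0.274 for oxidative phosphorylation.

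In all, 3022 genes changed at 24 h, 1652 higher and 1370 lower, and 18 lists were called. Of these genes, 664 changed 2-fold or more. The count was 6414 without DMSO 6 h replicate 2 and 6207 with only the 6 libraries compared. It was 1712 without DMSO replicate 2, 1681 without DMSO replicate 3, and 1920, 1887 and 1914 without GSK-J4 replicate 1, 2 or 3. Scaling by library size alone gave 2029 higher and 1019 lower genes.

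**Figure D3:**
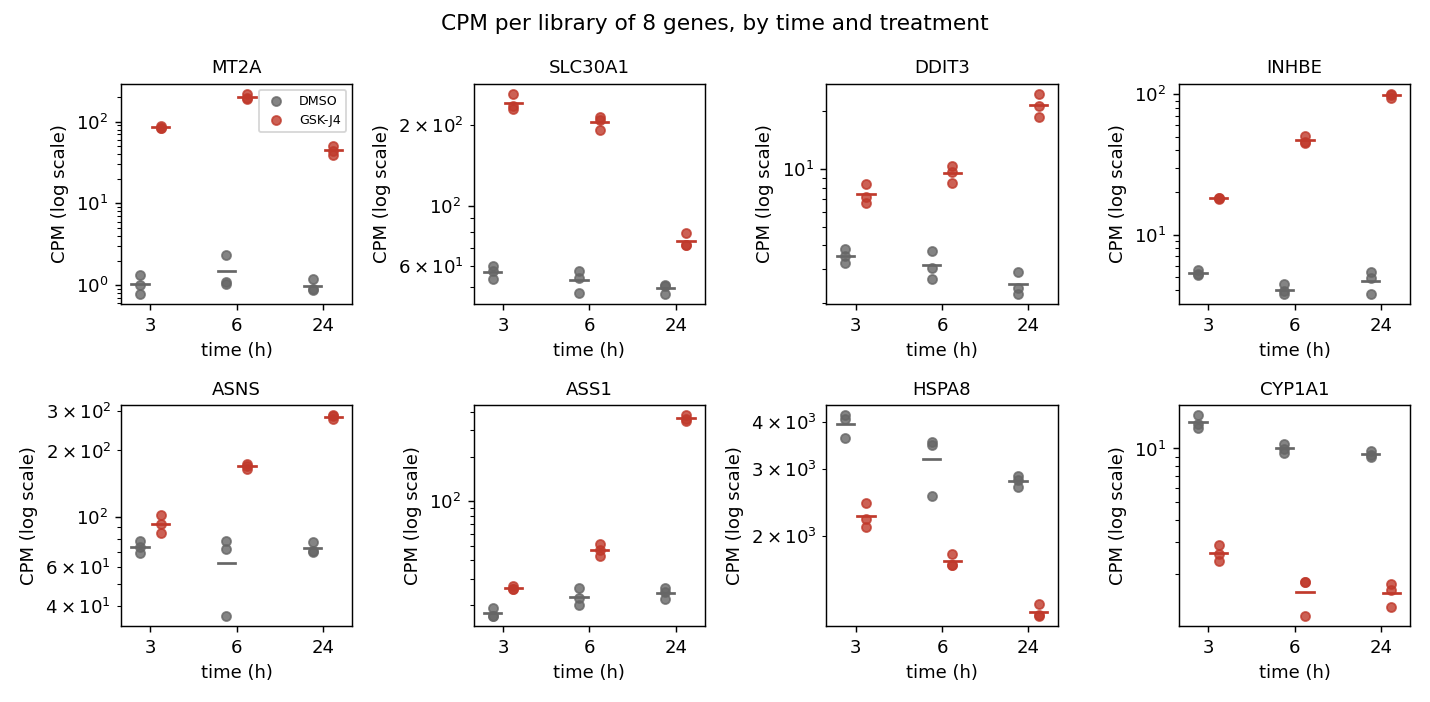
Points are CPM (log axis) of each library for 8 genes by time in h, with DMSO in grey and GSK-J4 in red, and lines are means of 3 libraries. The mean of MT2A with GSK-J4 was 202 CPM at 6 h, against 85.3 at 3 h and 44.5 at 24 h.

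KDM6A and KDM6B, the enzymes that GSK-J4 inhibits, did not pass at any time. KDM6A had log2 fold changes of 0.14, 0.52 and 0.39 at 3, 6 and 24 h, and KDM6A at 24 h passed without DMSO 6 h replicate 2 (adjusted p = 0.0152, and 0.0152 to 0.418 over all alternatives). KDM6B had 0.32, -0.26 and -0.22. HMOX1, haem oxygenase, had -0.11, -0.05 and 0.05. IRF4, a transcription factor of plasma cells, had 0.17, 0.32 and 0.03. HSPA1A had 0 counts in all 18 libraries, and its near-identical copy HSPA1B had at most 0.161 CPM, so no level was taken from either.

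The effects of GSK-J4 were compared between times by the difference of the contrasts. Between 3 and 24 h, 638 genes differed, 374 more positive and 264 more negative at 24 h. ALOX5AP differed by 3.65, PIP5KL1 by 3.58 and ASS1 by 3.33 on the log2 scale. DDIT3 differed by 2.03 and ASNS by 1.61. SLC30A1 had a difference of -1.50, MT1X of -1.96 and PFKFB4 of -3.28. Between 6 and 24 h 187 genes differed, and MT2A had a difference of -1.84 (adjusted p = 0.00804). Between 3 and 6 h 7 differed, among them INHBE by 1.75 and SLC7A11 by 1.41. Without DMSO 6 h replicate 2 these counts were 3416, 1062 and 35. With any other library of the comparison left out they ranged from 327 to 744, 91 to 365 and 3 to 11. Camera called 18 lists between 3 and 24 h, and 8 held with an estimated correlation, among them ATF4 targets, with 16 of 31 members more positive at 24 h, and glycolysis, with 9 of 20 more negative. Metallothioneins as a list (adjusted p = 0.209 with an estimated correlation) were among those lost. Of the 31 genes higher at 3 h, 30 were higher at 6 h, where independent lists would share 0.552 (Fisher's exact test, two-sided, p = 2.24e-52). Of 292 higher at 6 h, 233 were higher at 24 h, where 29.4 would be shared (p = 1.96e-179, Fisher's exact test). Of 305 lower at 6 h, 159 were lower at 24 h, where 25.5 would be shared (p = 1.82e-90, Fisher's exact test), and all 13 lower at 3 h were lower at 6 h. Fisher's test takes genes as independent, while all times share the same fit, so these p-values overstate the evidence. Vehicle libraries also shared a GC trend, at 0.231 and 0.635 for DMSO 6 h replicates 1 and 2 and 0.321 and 0.31 for DMSO 24 h replicates 2 and 3. The remaining vehicle libraries had -0.298 and -0.233, and GSK-J4 -0.386 to -0.164. Its part in the overlap was not tested.

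**Figure D4:**
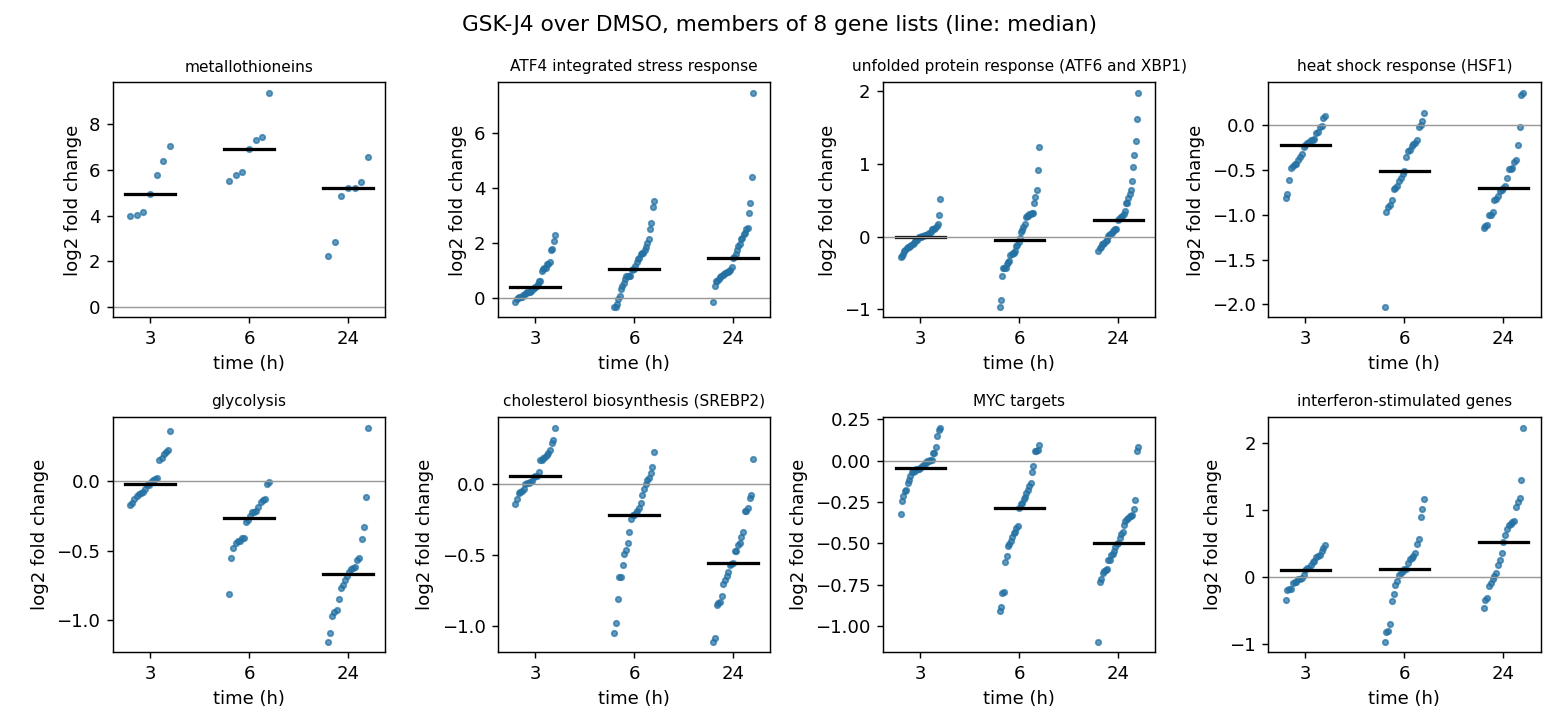
Each point is the log2 fold change, GSK-J4 over DMSO, of 1 measured member of a gene list at 3, 6 or 24 h, and lines are medians. The median of metallothioneins was 4.95, 6.90 and 5.21, and that of ATF4 targets 0.40, 1.07 and 1.43. With MT1M set to its bound the metallothionein medians were 4.18, 6.08 and 4.88. MT1E, not set to a bound, had 1 vehicle count at 24 h against 39 with GSK-J4, so the 24 h median stays uncertain. The order of the medians at 3 and 24 h is therefore not a result. Member by member, the median difference from 3 to 24 h was -0.542.

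Vehicle cells gave the background. Between DMSO at 3 and 24 h, edgeR called 11 genes, 6 higher and 5 lower at 24 h. PFKFB4, a regulator of glycolysis that hypoxia induces, was higher at 24 h by 1.93 on the log2 scale (SE 0.21, adjusted p = 0.000994), and its log2 fold change under GSK-J4 at 24 h, -2.85, was against this higher vehicle level. DNAJB1 was lower by a log2 value of -0.81. Both were chosen here after their values were seen. The count was 2924 without DMSO 6 h replicate 2, which was in neither group, 316 by DESeq2 and 4 with only the 6 libraries compared. With a library of the comparison left out it was 26 without DMSO 24 h replicate 1 and 3 to 5 otherwise. Between 6 and 24 h 3 genes differed, and 16 without DMSO 6 h replicate 2. Between 3 and 6 h edgeR called 0, with 2672 genes at an unadjusted p under 0.05, and DESeq2 called 2. Leaving out DMSO 6 h replicate 3 gave 3782.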

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

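The tests of RNA of other cells in DMSO 6 h replicate 2 and of the falls at 6 h without that library were chosen after the result was seen.

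The effect of GSK-J4 differed between times, by a test of the difference itself. It differed for 7 genes between 3 and 6 h, 187 between 6 and 24 h and 638 between 3 and 24 h. From 3 to 6 h the fold change of MT1G grew by 1.69 on the log2 scale, MT1H by 1.95, INHBE by 1.75, SLC7A11 by 1.41 and SLC6A9, a glycine transporter, by 1.29. From 6 to 24 h it grew for ASS1 by 2.85, ALOX5AP by 3.11, PIP5KL1 by 3.05, MAN1C1 by 2.30, LAT2 by 2.15 and DDIT3 by 1.45. Over the same interval the difference was -3.29 for MT1X, -2.93 for MT1F, -2.23 for MT1G, -1.84 for MT2A, -1.36 for SLC30A1, -2.90 for PFKFB4 and -2.21 for the histone gene H2BC11. From 3 to 24 h it was 3.65 for ALOX5AP, 3.58 for PIP5KL1, 3.33 for ASS1, 3.01 for ENSG00000006075, 2.75 for ARHGAP9, 2.03 for DDIT3 and 1.61 for ASNS. It was -3.28 for PFKFB4, -1.96 for MT1X, -1.73 for H2BC11, -1.64 for the pseudogene HMGA1P2 and -1.50 for SLC30A1. Another 63 named genes differed between a pair of times.

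Lists also differed between 3 and 24 h. The median log2 difference was 0.865 for ATF4 targets, 0.326 for interferon-stimulated genes, 0.275 for tRNA synthetases, 0.25 for p53 targets, 0.228 for one-carbon metabolism and 0.221 for the unfolded protein response. It was -0.766 for glycolysis, -0.612 for cholesterol synthesis, -0.542 for metallothioneins, -0.442 for MYC targets, -0.372 for hypoxia, -0.336 for histones and -0.299 for heat shock. Mitosis had -0.15, DNA replication -0.142, oxidative phosphorylation -0.139, housekeeping controls -0.131 and proteasome -0.081. Of these 18 calls 10 were lost with an estimated correlation, which gave an adjusted p of 0.0647 for MYC targets, 0.0961 for heat shock, 0.117 for interferon-stimulated genes, 0.209 for tRNA synthetases and for metallothioneins and 0.275 for housekeeping controls. It gave an adjusted p of 0.41 for mitosis and for DNA replication, 0.593 for proteasome and 0.632 for oxidative phosphorylation.

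These differences were set against 60 splits of the libraries into treated and vehicle within each time. Counts as large as the real one came from 4 splits for 3 and 6 h, 6 for 6 and 24 h and 7 for 3 and 24 h, the real one included, and from 5 for the 18 lists, so chance was not excluded by this test. The highest other counts were 342, 4587 and 1036 genes and 19 lists, but 342 and 4587 came from splits that exchanged treated and vehicle at 1 time and left both times unmixed, which adds both effects and does not measure chance. Without these, 2, 4 and 6 other splits were as large, with highest counts of 123, 954 and 1036 genes, and each kept the labels of 1 time unmixed, while 0 with both times mixed were as large and the median of the others was 0. A split that keeps 1 time unmixed still holds that time's effect, so such counts may come from real effects, which was not tested apart from chance. Splits with both times mixed add real effects to the spread within groups, so their low counts do not measure chance either.

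Between GSK-J4 and DMSO at one time, 10 splits of the 6 libraries are too few for a share under 0.05. The real split had 44 genes at 3 h, 597 at 6 h and 3022 at 24 h against a highest other of 0 each time, so 1 split of 10 gave as many. Every other split mixed treated and vehicle libraries in both its groups, which adds a treatment effect to the spread. Its count of 0 therefore does not measure chance. For lists the real counts were 9, 10 and 18, and the other splits called 2 to 9, 3 to 9 and 9 to 16. As large were 2, 1 and 1 splits, the real one included. Camera with the preset correlation thus also called lists under mixed labels, in every split. Mixed splits can hold part of a treatment effect, so these counts of lists do not measure chance. For DMSO at 3 and 6 h all 10 splits reached the real count of 0 by edgeR, where 2672 genes had an unadjusted p under 0.05 and DESeq2 called 2, and the highest other was 6. For DMSO at 6 and 24 h 2 splits reached 3, the real one and one that called 735. That one set DMSO 24 h replicate 1 and 6 h replicates 1 and 3 against 24 h replicates 2 and 3 and 6 h replicate 2. Their correlations with GC content were -0.233, 0.231 and -0.298 against 0.321, 0.31 and 0.635. Mitochondrial shares were 3.58%, 1.99% and 3.46% against 1.01%, 1.27% and 0.46%. The split thus followed these measures of the libraries and not time, though neither was tested as its source. For DMSO at 3 and 24 h 1 split reached 11 and the highest other was 0.

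DMSO 6 h replicate 2 stood at an SD of 0.891 from the rest of its group. Other libraries thinned to its 5.43 M counts reached at most 0.312, which argues against depth, and removing the GC trend left 0.682, which argues against that trend as the whole cause. RNA of other cells may have been present, since 8 genes had 5 or more counts there and 0 in the other 17 libraries. Notochord markers not picked from this library summed to 1.01 times the highest other library. That sum cannot decide, since LGALS3, at a median of 40.4 CPM in the other libraries, carries most of it there, so the question stays open. Genes detected numbered 28064 in this library at 5.43 M counts, and 24486 to 28568 in the others at 13.04 to 19.84 M, so its number was high for its depth. KRT8 was at 28.7 against at most 6.90 CPM elsewhere, KRT18 at 19.0 against 11.9 and SOX9 at 4.60 against 0.424. MIA and FOXA2 were at 0.184 CPM each there, against at most 0.113 and 0.0627 elsewhere. In a library of 5.43 M counts such levels rest on too few counts to say anything. Sums over lists fixed beforehand were at 209.2 against at most 135.9 for epithelial (KRT8 included), 3.87 against 1.21 for monocyte and 14.6 against 11.7 for T and NK cell markers. LGALS3 was at 15.8 against a highest other of 51.1, and fibroblast, erythroid and mature B cell sums were not the highest. Of 305 genes that fell at 6 h, 229 also fell without this library, but of 53 that fell 2-fold or more, 11 did, and no biological explanation was tested.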

How the results depend on the processing

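The correction for GC content, alone or with DMSO 6 h replicate 2 out, and the fits without that library of comparisons that do not hold it, and of the overlaps, were chosen after the result was seen. Of the values for genes under the alternatives set beforehand, 4874 kept direction and side of the threshold, 423 fell short of it, 110 newly passed it, 1 was reversed, and 27 changed sign without passing in either fit. For lists these numbers were 1851, 81, 50, 1 and 61. No called value changed sign under another scaling. The cause was not tested for any change below, except that a 2-fold minimum and a stricter p can only lower a count. The common coefficient of variation of the fit was 0.148 with all libraries and 0.0846 without DMSO 6 h replicate 2. A smaller shared spread can raise counts also in comparisons that do not hold that library. Libraries of 5.43 to 19.84 M counts limit what can be said of genes near the floor of 3 counts.

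Reversed values were ATF4 at 6 h, 0.56 without DMSO 6 h replicate 2 (-0.27 to 0.56 with any 1 library left out) and 0.624 with the GC trend also removed, and the list ribosomal proteins at 3 h, where the adjusted p was 0.765 without DMSO 3 h replicate 2 (8.98e-07 to 0.765 with any 1 library left out).

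Genes changed at 3 h numbered 44, and 83 by DESeq2, 114 without DMSO 6 h replicate 2, 148 with the GC trend also removed, 25 at a 2-fold minimum, 26 at an adjusted p under 0.01 and 27 to 36 with a library of the comparison left out. At 6 h they numbered 597, and 1968 with no filter, 1044 with the GC trend removed, 2381 by DESeq2, 26 in a fit of only the groups compared, 140 at 2-fold, 158 at 0.01 and 164 to 4637 with a library left out. At 24 h they numbered 3022, and 6414 without DMSO 6 h replicate 2, 6415 with the GC trend also removed, 6207 with only the groups compared, 664 at 2-fold, 1469 at 0.01 and 1681 to 2931 with a library left out. By library size alone the share that was higher went from 48.9% to 64.3% at 6 h, where it was 33.6% by DESeq2, 92.3% with only the groups compared and 33.9% to 76.6% with a library of the comparison left out, and from 54.7% to 66.6% at 24 h.

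Genes whose effect differed between 3 and 6 h numbered 7, and 211 with no filter, 26 with the GC trend removed, 45 without DMSO 6 h replicate 2 as well, 40 by DESeq2, 3 with only the groups compared, 3 at 0.01 and 3 to 35 with a library left out. Between 6 and 24 h they numbered 187, and 289, 673, 1411, 571 and 57 under the same first 5 alternatives, 82 at 2-fold, 64 at 0.01 and 91 to 1062 with a library left out. Between 3 and 24 h they numbered 638, and 1387 with the GC trend removed, 3333 without that library as well, 3416 without it alone, 1223 by DESeq2, 3191 with only the groups compared, 231 at 2-fold, 214 at 0.01 and 327 to 744 with a library left out.

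Genes that differed between DMSO at 3 and 6 h numbered 0 by edgeR (2672 at an unadjusted p under 0.05), and 867 with no filter, 3 with the GC trend and DMSO 6 h replicate 2 removed, 2 by DESeq2 and 0 to 3782 with a library left out. Between DMSO at 6 and 24 h they numbered 3, and 314 with no filter, 7 with the GC trend removed, 19 without that library as well, 40 by DESeq2, 0 with only the groups compared (2236 at an unadjusted p under 0.05 in the full fit), 1 at 2-fold, 1 at 0.01 and 1 to 16 with a library left out. Between DMSO at 3 and 24 h they numbered 11, and 5 with DESeq2 size factors, 481 with no filter, 62 with the GC trend removed, 2517 without DMSO 6 h replicate 2 as well, 2924 without it alone, 316 by DESeq2, 4 with only the groups compared, 5 at 2-fold, 4 at 0.01 and 3 to 26 with a library left out.

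Lists called at 3, 6 and 24 h numbered 9, 10 and 18, and 4, 2 and 10 with an estimated correlation. With a library left out they ranged from 7 to 10, 8 to 16 and 18 to 18. For the difference between 3 and 24 h there were 18, 8 with an estimated correlation and 14 to 18 with a library left out.

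Genes higher at both 3 and 6 h numbered 30, and 18 at 0.01 and 57 without DMSO 6 h replicate 2, and genes lower at both 13, and 6 at 0.01, 2 at 2-fold and 34 without it. For 6 and 24 h, 233 were higher at both, and 106 at 0.01, 75 at 2-fold and 364 without that library, and 159 lower, and 29, 14 and 255 in the same order. For 3 and 24 h, 28 were higher at both, and 18, 18 and 56, and 9 lower, and 5, 2 and 28.

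No pairing of the libraries by the label number was detected, though the check cannot exclude it, since vehicle libraries of a group differed in their GC trend. Same-numbered treated and vehicle libraries deviated together at correlations of -0.218 to 0.18, and not every library correlated best with its own number. With the number as a replicate block, 36, 580 and 2768 genes changed at 3, 6 and 24 h, 4 differed in effect between 3 and 6 h, 1 differed between DMSO at 6 and 24 h and 4 between DMSO at 3 and 24 h.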

Other observations

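All 6 lists described here, and the test of AHR targets, were chosen after the result was seen. Amino acid transporters rose, with 2 of 18 members higher at 3 h and 8 at 6 h (adjusted p = 0.0193 and 0.021 with an estimated correlation), and 10 higher and 2 lower at 24 h (adjusted p = 0.191 with an estimated correlation). Some of them, SLC7A11 among them, are also ATF4 targets. SLC6A9, which carries glycine, rose by 2.85 on the log2 scale at 24 h, and SLC7A5, which carries leucine, by 0.93. Of 10 fatty acid synthesis genes 4 fell at 24 h (adjusted p = 0.192 with an estimated correlation), FASN, fatty acid synthase, with a log2 fold change of -1.28.

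Among 5 BMP and ID targets at 24 h, 2 rose and 2 fell. Camera did not call the list (adjusted p = 0.721 with the preset), while fry, which asks whether members move on balance one way, had it higher at 3, 6 and 24 h (adjusted p = 0.0163, 0.00697 and 3.54e-05). BAMBI, a decoy receptor for BMP and TGF-beta ligands, had log2 fold changes of 1.10, 1.85 and 2.84 at 3, 6 and 24 h, while ID1 had -1.01 and ID3 -1.39 at 24 h. Of 8 haem synthesis genes, ALAS1, the first enzyme of the pathway, rose by 0.45, 0.63 and 0.31, and CPOX had -0.51, -0.57 and -0.25, and neither camera nor fry called this list at any time. Notochord and chordoma markers had 0 of 10 members passing by edgeR at any time with all libraries, and LGALS3 higher and TBXT lower at 24 h without DMSO 6 h replicate 2. At 6 h 7 were lower adjusted over the list alone, and the list had an adjusted p of 0.0104 with the preset and 0.484 with an estimated correlation, and its median log2 fold change was -2.49 with DMSO 6 h replicate 2 and -0.19 without it, from which 7 of its genes had been picked.

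CYP1A1 and CYP1B1 fell at all 3 times, with log2 fold changes of -2.55 and -1.54 at 24 h, and a hypothesis was that transcription of AHR targets may be lower in general. The list of 8 measured AHR targets, which holds both, was lower at 3 h (adjusted p = 0.000104 with the preset and 0.00637 with an estimated correlation; 4 lower and 2 higher adjusted over the list alone), and was not called by camera at 6 h (0.316) or 24 h (0.891), though fry had it lower at 6 h (adjusted p = 1.52e-05) and not at 24 h (0.152). Of the 6 other targets, 0 fell and 1 rose at 3 h, 1 fell (AHRR, a feedback repressor, with -0.91) and 2 rose at 6 h, and 0 fell and 2 rose at 24 h by edgeR. Without DMSO 6 h replicate 2 the whole list had 4 lower and 2 higher at both 3 and 6 h and 3 of each at 24 h, where TIPARP had -0.36, so that 0 does not hold in that fit, though most of the other targets did not fall at 24 h in either. SLC7A5 and STC2, the 2 that rose, are also among the ATF4 targets and say little of AHR, and since the genes that prompted the list weigh in its call at 3 h, a fall at the earlier times stays open.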
